A study of Arabidopsis thaliana with 8 samples.

How the data were processed

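Seedlings of Arabidopsis thaliana Columbia-0 and of the mutant atalkbh10b-1, aged 14 days, were sampled per the labels as biological replicates, with 2 pull-down and 2 input libraries for each of the 2 genotypes, 8 in all. Per the labels' protocols, poly(A) RNA was fragmented, incubated with an antibody against m6A and eluted with free m6A, and libraries were made from the eluate and from input RNA. Where replicates are named as biological, nothing further says whether they were grown or sequenced apart, so the tests measure the spread between these libraries.

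The authors deposited 1 peak list per genotype. Each row holds a gene, a start, an end and, per the file headers, a log2 value of enrichment for each replicate. Per the submitters' processing notes, TopHat2 2.0.14, edgeR and the genome build TAIR10 were used, with no role given for any of them. The peak caller, its thresholds, the formula of the enrichment, the scaling of the libraries and whether introns count in the positions are not given in the sources used here. If the authors scaled each library to a common level, a difference shared by all peaks would have been removed before deposit. The values of a pair of overlapping peaks come from the borders of each list, which need not coincide. Because a peak had to be listed to have a value, enrichment below the authors' threshold is missing from both lists.

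The headers name 3 replicates, R1, R2 and R3, and the labels have samples for 2 of them. The 2 columns of the third replicate, 1 per list, match no sample and were not used. In 20447 of the 20521 wild-type peaks and 20629 of the 20696 mutant peaks at least 1 of the 2 replicates used had a log2 enrichment of 1 or more, and in 31.4% and 35.1% exactly 1 of them did, so a peak can rest in part on the replicate not used. Depth is unknown, since no counts were used, and no interval that needs it is given. Intervals on shares of peaks are exact binomial 95% intervals and cover counting error only.

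A peak counted as shared where it overlapped a peak of the other list, in the same gene, by at least 1 base. For enrichment, pairs in which each peak was the other's largest overlap were kept. The deposited log2 values were used as they are, with no pseudocount, although a pseudocount of 1 had been planned for values on a linear scale. A ratio of 1.5 between genotype means was called higher or lower. Genotypes were compared at each pair with limma 3.58.1 in R 4.3.3 (moderated test on the 4 values, no replicate block, Benjamini-Hochberg adjustment, threshold 0.05). A gene's difference is the mean over its shared pairs. The fit was tested on simulated values in which each pair's own estimated replicate spread was taken as its true spread. It called 0 of 50 pairs at each log2 shift of 1, 2, 4 and 8. With a spread 10 times smaller it called 20, 37, 45 and 50 of 50, with 5 false calls among 13676 unshifted pairs. Whether replicate numbers pair the libraries was checked from the correlation of their deviations.

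The 12 gene lists were m6A machinery, flowering time, circadian clock, nuclear photosynthesis, shoot meristem and leaf polarity, trichome fate, auxin response and transport, photoreceptors and light signalling, small RNA pathway and mRNA decay, abscisic acid and abiotic stress, root markers, and reference transcripts, 252 genes in all. They, the tests and the rule for named genes were fixed before the data were examined. Each list was tested for genes listed in 1 genotype alone by two-sided Fisher's exact tests against all 14304 genes listed in either genotype, adjusted over lists and directions. Lists with at least 5 genes at a shared pair were set among 10000 random gene sets matched in 10 bins of mean enrichment. Gene symbols came from a table of the TAIR10.1 assembly, which held 14192 of the 14304 genes and a symbol for 6677. It gave no symbol for 14 of the 252 list genes, which are named from general knowledge. The same table gave which genes overlap or neighbour each other; none of its coordinates are printed. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

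The rule named ALKBH10B first and FT, SPL3 and SPL9 in any case. Of the flowering-time and m6A machinery lists it named up to 8 members per direction with a peak in 1 genotype alone or a shared peak at least 1.5-fold apart, and up to 4 of each other list, by size. Among genes with a symbol, it added the 8 most enriched peaks of each genotype, taken here from genes listed in that genotype alone, and the 8 largest differences each way. Among all genes, it added the 6 shared peaks of highest mean enrichment. Some of these are named without values, and 1 is not reported here. Genes without a peak are named as examples chosen afterwards.

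Alternatives were other overlaps, stricter enrichment, equal numbers of peaks, genes that overlap no other gene, a ratio of 2, centring, gene-level means, leaving out each replicate, and a replicate block. Also tried, chosen after the data had been seen, were the top 10000 peaks, a log2 enrichment of at least 1 in both replicates, leaving out organelle genes, centring each replicate on its median and a spread that varies with enrichment. Another 22 gene families, found by symbol or genome, were tested only after the data had been seen. Sequence motifs and positions relative to start and stop codons were not analysed here.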

Results

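N6-methyladenosine (m6A), a methylated form of adenosine within messenger RNA, was mapped in Arabidopsis thaliana seedlings aged 14 days. Fragmented poly(A) RNA of the wild type Columbia-0 and of the mutant atalkbh10b-1 was pulled down with an antibody against m6A and sequenced beside input RNA that was not pulled down. The labels describe 8 libraries, 2 pull-down and 2 input libraries for each genotype, as biological replicates. The deposited values are the authors' lists of m6A peaks, 1 list per genotype, with a log2 enrichment of each peak in each replicate. The wild-type list held 20521 peaks in 12939 genes and the mutant list 20696 peaks in 12443 genes. The median peak was 157 bases wide in both lists. A single peak was listed for 60.2% of the wild-type genes and for 57.5% of the mutant genes, and the most in 1 gene was 14 in wild type (AT4G17140) and 15 in the mutant (AT2G28290). Positions below are bases along each gene's model as the lists count them, and the depth of the libraries is unknown from these values.

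The mutant carries a lesion in ALKBH10B (AT4G02940), which encodes an m6A demethylase of the AlkB family. Its own transcript was listed with peaks in both genotypes. One peak was shared, at bases 531 to 770 in wild type and 551 to 650 in the mutant, with a log2 enrichment of 1.19 ± 0.26 (SD, n = 2) in wild type and 2.52 ± 1.29 in the mutant. A peak at bases 951 to 1050 was listed in the mutant (1.28 ± 0.87), and one at bases 1751 to 1996 in wild type (0.94 ± 1.97), each with no overlapping partner. Enrichment over input measures methylation of the RNA that is present, not its amount, so these peaks do not check the loss of the gene. Of 3 flowering regulators fixed in advance, FT (AT1G65480), the mobile flowering signal, had a peak in the mutant list at bases 19 to 175, with log2 enrichments of 5.43 and 0.00 in the 2 replicates, and none in wild type. SPL9 (AT2G42200), a phase-change factor targeted by a microRNA, had a peak in the wild-type list at bases 961 to 1117, with 4.62 and -0.25, and none in the mutant. SPL3 had no peak in either list. The FT and SPL9 peaks thus each rested on 1 of the 2 replicates used. Whether the 0.00 of FT is a measured ratio or stands for a missing one is unknown, since the formula is not given.

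The first comparison asked which transcripts carried a listed peak in the mutant, in wild type or in both. A gene can also be missing from a list because its transcript was scarce in those seedlings. Transcript amounts were not examined, so a gene listed in 1 genotype or in neither is not thereby shown to differ in methylation. Flowering-time genes stood on both sides. Those listed in the mutant alone were GI, FT, SPL6, SPL13 and the FT repressors TEM1 and TEM2, and those listed in wild type alone were SPL9, SMZ, AP2 and CDF1, while 22 of the 47 flowering genes had peaks in both lists and 15 in neither, among them FLC, CO, LFY and AP1. TEM2 (AT1G68840) had close replicate values in the mutant, with a mean log2 enrichment of 4.82 ± 0.12, as did TEM1 (AT1G25560) with 2.11 ± 0.27, whereas GI reached 5.91 ± 5.15. In wild type, CDF1 (AT5G62430), a repressor of CO, had 3.57 ± 0.54 and AP2 had 4.86 ± 2.01. SPL13 has a near-identical copy, so its peak is uncertain.

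Among the 22 genes of the m6A machinery, 16 were listed in both genotypes, ECT10 (AT5G58190), which encodes a reader protein with a YTH domain, in wild type alone (8.31 ± 0.99), and 5 in neither. Clock genes listed in the mutant alone were RVE8 (5.18 ± 4.61) and PRR5 (4.45 ± 1.42), and CHE was listed in wild type alone (1.63 ± 0.34). CCA1, LHY, PRR7, PRR9 and LNK1 had no peak in either list, and 10 of the 18 clock genes were listed in both. Of 16 genes of the shoot meristem and leaf polarity, CLV2 was listed in the mutant alone (3.25 ± 1.2), AS1 (1.63 ± 0.20) and KNAT1 (2.07 ± 2.31) in wild type alone, 4 in both and 9 in neither. Of 10 trichome genes, TTG2 (4.80 ± 4.01) was listed in the mutant alone, MYB23 (3.05 ± 0.63) in wild type alone and 3 in both. Root markers divided likewise. SHR, which specifies the endodermis, had 7.95 ± 1.02 in the mutant, and COBL9 had 5.80 ± 3.88. MYB36 (3.75 ± 0.41) and PHT1;1 (1.21 ± 1.11) were listed in wild type alone, and 3 of the 12 root genes were listed in both.

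Other groups were listed almost entirely in both genotypes. All 18 genes of the small RNA pathway and mRNA decay and all 13 reference transcripts had peaks in both lists, as did 21 of 22 auxin genes. Of 33 nuclear photosynthesis genes, 29 were in both lists and 2 in wild type alone, RCA (0.93 ± 0.23) and LHCB1.2 (0.90 ± 0.34), the latter uncertain because near-identical copies lie beside it. Of 21 light-signalling genes, 17 were in both lists, the phytochrome gene PHYD in the mutant alone (4.25 ± 2.25) and HY5 in wild type alone (1.61 ± 2.74). All 15 listed genes of the abscisic acid and stress group were in both lists, and the other 5, including CBF1, CBF2 and CBF3, were in neither. Over the 12 groups, 171 of 252 genes had peaks in both lists, 14 in the mutant alone, 14 in wild type alone and 53 in neither.

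**Figure D1:**
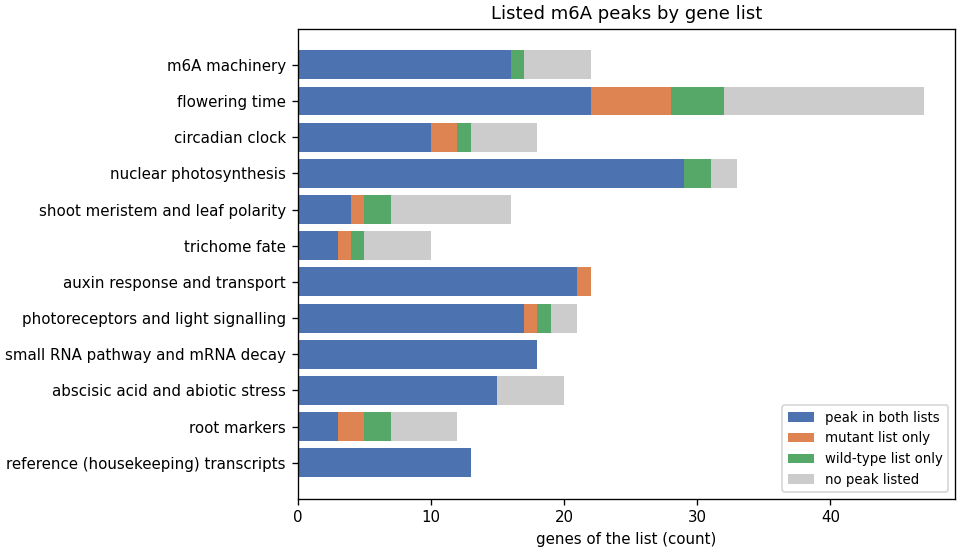
Horizontal bars give the number of genes in each of 12 gene groups (x axis, count) whose peaks were listed in both genotypes, in the mutant alone, in wild type alone or in neither. Flowering-time genes divide into 22, 6, 4 and 15, and the mutant-only and wild-type-only segments hold 14 genes each over all groups.

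None of the 12 groups passed a test for being over- or under-represented among the genes listed in the mutant alone or in wild type alone. In 24 two-sided Fisher's exact tests against all 14304 genes listed in either genotype, the smallest Benjamini-Hochberg adjusted p was 0.673, and no unadjusted p was under 0.05. With both directions counted as 1, a test chosen after the data had been seen, 5 groups had fewer such genes than the background at an unadjusted p under 0.05 (small RNA and mRNA decay, photosynthesis, abscisic acid and stress, auxin, and reference transcripts), and none passed, the smallest adjusted p being 0.0959 over 34 groups. Counted by peaks in place of genes, 2 of the 24 tests passed: 3 of 39 mutant peaks in photosynthesis genes lacked a partner (7.69%, against 30.7% of all mutant peaks, adjusted p = 0.0196), and 10 of 14 wild-type peaks in meristem genes did (71.4%, against 30.6%, adjusted p = 0.0235). Genes and peaks are not replicates, so these tests describe the 2 lists.

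Outside the groups, the most enriched peaks of genes listed in the mutant alone lay in TT7 (AT5G07990), a flavonoid hydroxylase gene, with a log2 enrichment of 10.55 ± 0.81, in RUP2 (AT5G23730), a regulator of the UV-B receptor, with 10.11 ± 1.35, in the cell-cycle kinase gene CDKB1;1 (9.89 ± 0.60), and in ARAD1, SIEL, ABCI17, ORC4 and OZF1, between 9.14 and 9.31. Those of genes listed in wild type alone lay in SSP4b (AT4G18140, 10.24 ± 0.38), the SUMO ligase gene HPY2 (AT3G15150, 10.11 ± 1.67), PARP1 (9.89 ± 1.00), ARL2, SNI1, UP6, CHX17 and EMB2261, the last at 9.29 ± 1.40. Input reads were not examined, so how far values this high rest on few input reads is unknown.

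Over all genes, 11078 had peaks in both lists, 1365 in the mutant list alone and 1861 in the wild-type list alone. Of the 27562 protein-coding genes, 10903 were in both lists, where independent draws from all of them would share 5626, a value that counts genes not expressed in seedlings and is low for that reason. By position, 14245 wild-type peaks (69.4%, exact binomial 95% interval 68.8 to 70.0, counting error only) overlapped a mutant peak by at least 1 base, and 14340 mutant peaks (69.3%) overlapped a wild-type peak. The peaks without a partner numbered 6276 in wild type and 6356 in the mutant, of which 64.4% and 74.4% lay in a gene with a peak elsewhere in the other list. With 1 list per genotype, no gained or lost peak has a replicate check of its own. The 1365 and 1861 genes became 884 and 1207 where both replicates of the listed genotype had to reach a log2 enrichment of 1.

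Peaks without a partner repeated less well between replicates than shared ones. Shared peaks had a median log2 difference between replicates of 1.26 in wild type and 1.61 in the mutant, and peaks without a partner 2.1 and 2.33. Across peaks, which are not independent replicates, Spearman's correlation of the replicates was 0.319 in wild type and 0.183 in the mutant for shared peaks, and 0.00637 and -0.0299 for peaks without a partner. In genes listed in 1 genotype the median differences were 2.82 and 3.31.

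The second comparison asked whether enrichment differed between the genotypes at the 13876 pairs of overlapping peaks, which lay in 10607 genes. Flowering-time genes again had values in both directions, with 12 peaks at least 1.5-fold higher in the mutant, 15 at least 1.5-fold lower and 9 between. FCA, FY, FPA, FVE and LD, known from the autonomous pathway that represses FLC, were divided between the directions. FCA (AT4G16280) had 8.87 ± 1.55 in the mutant against 1.2 ± 3.79 in wild type, FY (AT5G13480) had 8.79 ± 1.70 against 2.66 ± 1.60, and FPA (AT2G43410), at bases 3064 to 3184 in wild type, had 8.50 ± 0.33 against 4.05 ± 1.89. FKF1 (AT1G68050), a blue-light receptor of the photoperiod pathway, had 4.81 ± 0.54 against 1.25 ± 1.23. At these 4 peaks both mutant values lay above both wild-type values. Further higher values were those of FVE at its first peak, TOE1, FLM and SNZ.

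Lower values lay in FRI, an activator of FLC, with 2.02 ± 4.53 in the mutant against 5.45 ± 1.18, in SPL10 with 3.29 ± 7.14 against 6.32 ± 1.24, and in VRN1 (AT3G18990), required for vernalization, with 1.40 ± 0.57 against 3.85 ± 0.70. LD and the floral repressor SVP also had lower values. FPA, TOE1 and FVE each had another peak with the opposite sign. The second FPA peak, at bases 3364 to 3464 in wild type, had 4.07 ± 6.21 in the mutant against 7.44 ± 1.34. No flowering peak passed with limma's test, either over all pairs or adjusted over the list alone, where the smallest adjusted p was 0.268. At an unadjusted p under 0.05 stood 4 peaks, those of FCA, FY, FPA and FKF1.

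**Figure D2:**
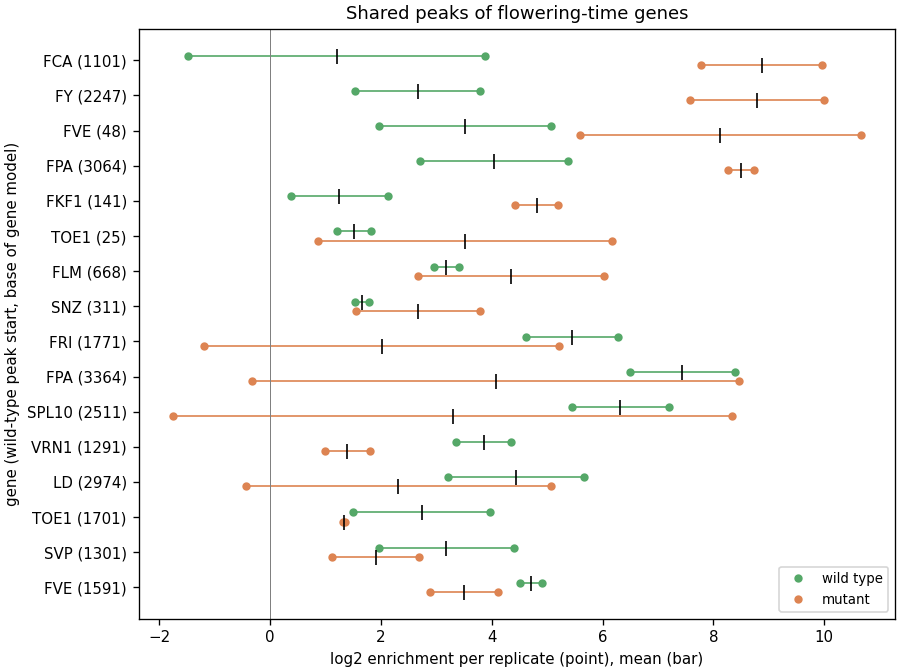
Each row is a shared peak of a flowering-time gene, with the start of its wild-type peak in bases. The x axis is log2 enrichment, points are the 2 replicates of wild type and mutant, lines join the replicates and black bars are their means, from FCA (1.2 in wild type, 8.87 in the mutant) down to FVE at base 1591 (4.71 and 3.50).

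In the m6A machinery 9 of 25 shared peaks had values at least 1.5-fold higher and 7 lower. The reader gene ECT4 had 5.65 ± 5.30 in the mutant against 0.37 ± 2.14 in wild type, and the methyltransferase gene MTA had 7.37 ± 4.71 against 5.10 ± 2.89. MTB (AT4G09980), the partner subunit of MTA, had a peak at bases 771 to 900 with 2.54 ± 0.19 against 1.03 ± 0.62 and another, at bases 358 to 491, with 1.33 ± 1.44 against 5.46 ± 4.37. VIR, a component of the writer complex, likewise had 1 peak with each sign. ECT3 and ECT8 stood among the higher values, and ECT5, ECT6 and HAKAI among the lower. The smallest adjusted p over the list alone was 0.794, with 0 peaks at an unadjusted p under 0.05.

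Light-signalling genes had 5 higher and 10 lower peaks of 28. The photoreceptor genes PHYA (AT1G09570, 0.71 ± 1.1 in the mutant against 5.15 ± 1.65 in wild type) and CRY2 (AT1G04400, 0.63 ± 1.07 against 5.01 ± 0.49) had the lowest mutant values relative to wild type, while PHYB had 6.19 ± 1.75 against 5.16 ± 0.96 and SPA4 5.05 ± 5.08 against 2.07 ± 1.18. Clock genes had 3 higher and 4 lower of 12, among them LNK2 (AT3G54500), with 4.97 ± 1.47 against 8.64 ± 0.64, and LUX, with 5.52 ± 5.34 against 1.80 ± 0.07. Of 36 auxin peaks, 12 were higher and 13 lower, with the response factor genes ARF1 (AT1G59750) at 6.19 ± 0.41 against 2.87 ± 0.41 and ARF8 at 2.32 ± 0.68 against 4.77 ± 2.46. The small RNA and mRNA decay genes had 8 higher and 13 lower of 33. UPF1 (AT5G47010), a factor of nonsense-mediated decay, had 2.25 ± 1.29 against 5.21 ± 0.15, and XRN4, a cytoplasmic exonuclease gene, had 8.49 ± 3.74 against 3.88 ± 3.41.

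The abscisic acid and stress genes had 6 higher and 8 lower peaks of 19, with ABI2 at 6.99 ± 5.13 against 2.67 ± 0.78 and SNRK2.2 at 0.38 ± 1.53 against 2.3 ± 0.23. The 3 shared peaks of trichome genes, in GL2, GIS and TTG1, all had lower mutant means, as in GL2 with 2.2 ± 2.42 against 5.55 ± 1.55. Meristem genes had 0 higher and 2 lower of 4 (PHV and PHB), and root genes 1 higher (SCR, 3.09 ± 1.26 against 0.75 ± 0.88) and 2 lower (CASP1 and IRT1) of 4. Reference transcripts, used as controls for stable expression, had 4 higher and 5 lower of 17. SAND (AT2G28390) had 6.23 ± 0.58 against 2.54 ± 0.10, and ACT2 had 2.23 ± 0.15 against 3.36 ± 0.08. The log2 difference of SAND (3.69) was as large as that of FKF1 (3.56).

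Nuclear photosynthesis genes had the closest values of the 12 groups. Of their 36 shared peaks, 33 (91.7%) lay within 1.5-fold between genotypes, against 35.3% of all other pairs, a difference tested only after the data had been seen (two-sided Fisher's exact test, adjusted p = 7.53e-11 over 29 groups). The median difference between their replicates was 0.29 on the log2 scale, below all 10000 random peak sets of equal enrichment, whose central 95% ran from 0.89 to 1.70. Neither comparison was matched on transcript abundance or read coverage, since no counts were used. Whether coverage accounts for the close values was not tested, so they are not shown to be a trait of methylation in these genes. The exceptions were the antenna genes LHCB3 (6.08 ± 4.02 against 4.01 ± 1.47), LHCB2.2 and LHCB2.1, of which the last 2 are near-identical to each other.

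Over 253 shared peaks of the 12 groups, 62 were higher and 83 lower in the mutant by at least 1.5-fold, and 0 passed when adjusted over the list alone. For the 9 groups with at least 5 genes at a shared pair, the median log2 difference per gene (mutant minus wild type) was set among 10000 random gene sets matched on enrichment. All 9 stood within the central 95% of these sets, from the 22.9th for the m6A machinery (median -0.29) to the 90.0th for auxin genes (0.34), with flowering-time genes at the 60.8th (0.06) and photosynthesis genes at the 70.9th (0.00). With the mean over all peaks of a gene in place of its shared pairs, the sign of the median turned in 6 of the 9 groups, all still within the central 95%: auxin genes then had -0.34 (percentile 14.6), the m6A machinery 0.09 (percentile 65.5) and flowering-time genes -0.12 (percentile 36.5).

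The largest differences over all genes with a symbol included several with close replicates. NF-YC9 (AT1G08970), a subunit of the nuclear factor Y complex, had 9.42 ± 0.24 in the mutant against 1.16 ± 0.25 in wild type. AGL16 (AT3G57230), a MADS-box factor, had 11.43 ± 1.47 against 2.98 ± 0.65, and the replication factor gene PSF1 (AT1G80190) had 10.55 ± 1.52 against 2.14 ± 0.03. INDH had 9.09 ± 0.84 against 0.95 ± 1.63. PAP10, FHY3, PFK4 and NAGS1 completed the 8 highest. In the opposite direction VPS20.1 (AT5G63880), a membrane-sorting component, had 2.60 ± 1.3 against 9.85 ± 0.80, and the triterpene synthase gene LUP2 (AT1G78960) had 5.16 ± 4.29 against 13.87 ± 0.92, with ARPC1B, EMB2766, NAC053, LNO1, CRLK2 and KAT5 beside them. The peaks of highest mean enrichment in both genotypes lay in EHD2 (10.09 ± 0.64 in wild type, 11.45 ± 3.14 in the mutant), AT5G24970, AT2G03667, PK3, LUP2 and AT3G12860. These are the extremes of 13876 pairs, and 0 of them passed after adjustment. Here too, values this high may rest on few input reads, which were not examined.

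Across all pairs the mutant had at least 1.5-fold higher enrichment at 4502 (32.4%), at least 1.5-fold lower at 4455 (32.1%) and values between at 4919 (35.4%). The median log2 difference was -0.02, a fold of 0.983, with quartiles of -0.90 and 0.95 and a median standard error of 1.24. The replicate medians were 2.5 and 2.62 in wild type and 2.52 and 2.44 in the mutant (exact permutation test, two-sided, p = 0.667, where 2 against 2 cannot go below 0.333). With limma, 0 pairs passed at an adjusted p of 0.05, the smallest being 1.00, and 491 (3.54%, 286 higher and 205 lower) had an unadjusted p under 0.05. Both mutant values lay above both wild-type values at 13.7% of the pairs and below at 15.03%, where 4 exchangeable values would give 16.7% each. The 4 values are not exchangeable, because each list held peaks chosen within its own genotype.

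Libraries of different genotypes lay about as far apart as the wild-type replicates, and closer together than the mutant replicates. Across pairs, Spearman's correlation was 0.320 between the wild-type replicates and 0.187 between the mutant replicates, and 0.324 to 0.348 between libraries of different genotypes. The median difference between single libraries was 1.26 within wild type, 1.60 within the mutant and 1.28 between genotypes. Because peaks were chosen within each genotype, which can set its own replicates apart, distances within and between genotypes are not on an equal footing. The test had little power in a simulation that took each pair's own estimated spread as its true spread. There it called 0 of 50 pairs shifted by a log2 difference of 8. Spreads set in this way are more uneven than true ones, and 820 of 13676 unshifted pairs had an unadjusted p under 0.05 with limma. The simulation is thus a rough guide to power. The count of 0 in the real data does not show that enrichment was alike.

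**Figure D3:**
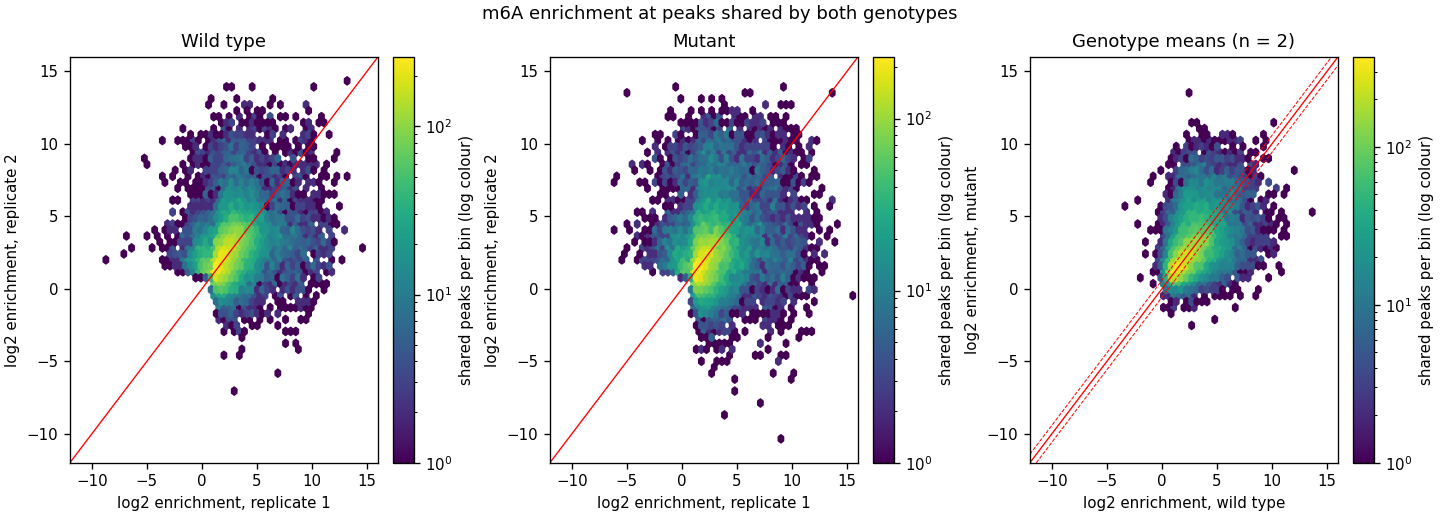
Density of the 13876 shared pairs on log2 enrichment axes, for the 2 replicates of wild type, the 2 replicates of the mutant, and the genotype means. The solid line marks equality and, in the last panel, dashed lines mark 1.5-fold. The first 2 panels set single libraries against each other, with Spearman's correlations of 0.320 and 0.187, and the last sets means of 2, so the widths of the clouds are not comparable.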

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

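The alternatives of the top 10000 peaks, of a log2 enrichment of at least 1, of each replicate centred on its median and of a varying spread were chosen after the data had been seen. Of 83 alternative values, 56 stayed within a tolerance, which was 1.5 times for a count, the 95% binomial interval for a share and the SD of the 4 replicate medians (0.0776) for a median difference. Of the rest, 9 counts were lower, 5 were higher, and 13 shares or medians moved. The 56 include the counts of 0 from limma, a test with little power in the simulation, so their number does not measure robustness. The share of wild-type peaks with a mutant partner (69.4%) was 56.2% with a reciprocal overlap of at least 50%, 63.2% with 50% of the shorter peak, 73.1% with peaks up to 100 bases apart, 74.0% for the more enriched part of the wild-type list split at its median, 52.8% for the top 10000 peaks of each list, 58.9% with a log2 enrichment of at least 1 in both replicates of each list, 76.6% with that demand on wild type alone, and 60.4% to 65.5% without each replicate, with a log2 enrichment of at least 1 in the other. Genes listed in both, in the mutant alone and in wild type alone numbered 7178, 900 and 1220 among genes overlapping no other gene, by construction fewer, and 5736, 2396 and 2834 for the top 10000 peaks. With a log2 enrichment of at least 1 in both replicates and no peak in the full other list, 884 and 1207 genes remained in the mutant and in wild type. In each of these the wild-type-only genes outnumbered the mutant-only ones.

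The median log2 difference at shared pairs (-0.02) was 0.0851 without the lower part of the peaks by enrichment, 0.0567 with each replicate centred, and -0.135 to 0.0597 without each replicate, so its sign is not settled; the cause was not tested. Nor is the order of higher and lower pairs (4502 and 4455), which was 4676 and 5391 without mutant replicate 1. They numbered 2632 and 2345 with a log2 enrichment of at least 1 in all 4 values, a filter that leaves 8026 pairs. With limma, 0 pairs passed under every alternative run. The pairs at an unadjusted p under 0.05 numbered 491 in the original test, 451 to 1215 without each replicate, the highest without mutant replicate 1, where the lone mutant library is assumed to vary like the wild type, 1017 without mutant replicate 2, and 309 with a varying spread. With the replicate block, 0 passed and 568 had an unadjusted p under 0.05. Libraries with the same number did not deviate together from peak to peak (correlation 0.00678 across pairs). A shift common to all peaks would not enter this value, so whether the numbers pair the libraries stays unknown. The tests of gene lists gave 2 calls by peaks and 0 by genes; the cause was not tested.

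A threshold of 0.001 on p or false discovery rate, DESeq2 size factors, a filter on low counts, and the windows for codons and motifs were not run, since they need values or sequences not used here. What depth limits cannot be stated, because the depth is unknown.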

Other observations

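The tests below were chosen after the data had been seen, except those of peak borders, of regrouped replicates and of P450 genes without neighbours, whose criteria were written before their results. Among 22 gene families, the genes of the mitochondrial genome and the MYB transcription factors passed a test for being listed in 1 genotype alone, 16 of 23 (69.6%) and 17 of 30 (56.7%) against 22.6% of all genes (two-sided Fisher's exact tests, adjusted p = 6.91e-05 and 0.000914 over 34 groups). Most of these MYB genes were listed in wild type alone, 11 of 30 (36.7% against 13.01%, adjusted p = 0.0125), among them MYB1 (5.92 and 6.21 in the 2 replicates), MYB65 (6.01 and 5.22), MYB109 (6.52 and 8.09), MYB88 and MYB3R-5. MYB10 (3.78 and 9.91) and MYB45 were listed in the mutant alone. Of 29 plastid genes 10 were listed in the mutant alone (34.5% against 9.54%, adjusted p = 0.00489), at low enrichment, such as ATCG00020 with 1.54 and 1.16 and ATCG01050 with -1.24 and 0.96, and 4 of the 10 had a peak with a log2 enrichment of at least 1 in both replicates. The corresponding share of mitochondrial genes was 9 of 23 (39.1%), 4 of them with such a peak, and another 7 were listed in wild type alone, 6 of them with such a peak.

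Close values between replicates were not limited to photosynthesis genes. The median replicate difference was 0.86 for 39 genes of cytosolic ribosomal proteins, at percentile 0.04 of random peak sets of equal enrichment, and 0.59 for the reference transcripts, at percentile 0.02, whereas flowering-time genes (2.14) stood at percentile 92.9. The 6 shared peaks of the 5 plastid ribosomal protein genes found by symbol lay within 1.5-fold between genotypes (two-sided Fisher's exact test, adjusted p = 0.0144). Both ribosomal families were found by symbol alone, which can misplace members or leave them out. These comparisons, too, were not matched on transcript abundance.

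Cytochrome P450 genes, a family of oxidases in secondary and hormone metabolism, are counted here only where their symbol starts with CYP, which leaves out members with other symbols, such as TT7. Of 85 genes so named, 18 were listed in the mutant alone (21.2% against 9.54%, adjusted p = 0.0125) and 12 in wild type alone. Examples with high values in both mutant replicates are CYP87A2 (8.10 and 9.05), CYP78A5 (5.41 and 4.43), CYP705A12 and CYP71B24, and 10 of the 18, against 8 of the 12 in wild type, had a peak with a log2 enrichment of at least 1 in both replicates. At shared pairs 31 P450 peaks had values at least 1.5-fold higher in the mutant and 9 lower, and the median difference over 47 genes was 0.55, with 32 of 47 above 0. CYP71B11 (AT5G25120) had 10.88 and 8.43 in the mutant against 1.93 and 3.82, and CYP711A1 (AT2G26170), which acts in strigolactone synthesis, 6.72 and 8.59 against 0.16 and 2.24, while CYP79B3 had 2.96 and 0.50 against 10.04 and 5.23. None passed singly.

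For the P450 genes, chance in the draw of genes, over the 18 families with enough shared pairs, was argued against by the percentile of their median. It stood at 99.98 of 10000 random gene sets, with an adjusted p of 0.0072, although neighbouring genes are not independent draws. The random sets hold the same 4 libraries fixed, so this p does not measure the spread between libraries, and chance at that level is not argued against. Reads shared among neighbouring copies stay open as a candidate explanation, because the 18 P450 genes with no other P450 gene among the 5 on either side had a median of 0.60 but stood at percentile 95.45, inside the random range. Against this explanation, the 29 P450 genes with such a neighbour had the lower median, 0.38 (19 of 29 above 0, against 13 of 18), although they stood at percentile 99.325. The difference of the medians, with minus without a neighbour, was -0.21, and its 95% bootstrap interval over genes, from -1.70 to 0.35, leaves both directions possible. A single library also stays open: without mutant replicate 2 the median was 0.34, at percentile 95.345, the lowest of the 4, and without each of the others at percentile 98.2 or above. The median was 0.63 with each replicate centred. A higher methylation of P450 transcripts in the mutant is therefore a hypothesis. It was not separated from these, from chance in the draw of genes or from the spread between libraries.

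Peaks without a partner may owe much to low repeatability: in 18 of 20 bins of equal mean enrichment over both lists their replicates differed more than those of shared peaks, by a median excess of 0.61 in wild type and 0.51 in the mutant. A shift of peak borders was argued against, as 12.888% of them (95% interval 12.3 to 13.5) had a peak of the other list within 100 bases. A net gain of methylation without the demethylase cannot be told apart from none: 42.312% of the genes listed in 1 genotype were in the mutant list (95% interval 40.6 to 44.0), but so were 50.3% of the peaks without a partner (49.4 to 51.2). A lower sensitivity of the mutant libraries, whose depth is unknown, could also hide a gain and was not tested.

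Regrouping does not decide whether differences in enrichment at shared pairs exceed replicate spread. Regrouping the 4 values across genotypes gave 9303 and 9410 pairs at least 1.5-fold apart, against 8957 between the genotypes. Each list, however, held peaks chosen within 1 genotype: the higher replicate of a peak was at least 0.88 in wild type and 0.80 in the mutant. Such a choice can set replicates of 1 genotype apart and hold the genotype means together, which favours the regroupings in advance. A general rise of methylation without the demethylase cannot be told apart from no rise. The median log2 difference was -0.0244, but the scaling of the libraries is not stated, and scaling to a common level would remove such a rise.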
